A study of Mus musculus with 18 samples.

How the data were processed

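Total RNA of mouse cardiac tissue was depleted of ribosomal RNA and made into libraries with NEB kits, per the labels' protocols. The deposited values, taken here as FPKM, are 1 number per transcript and library as the authors computed them. The unit is not named in the files and was inferred from the values. Multiplied by transcript length from GENCODE M21, many low values fell near whole multiples of 1 step per library. Of values of up to 10 fragments, 41.5 to 55.4% were whole within 0.05. The step was chosen to fit the low values best, so a part of this share is built in. The length-weighted sum was 63.6 to 74.9% of the most that FPKM allows. The submitters' processing notes name limma. Aligner, assembler, genome build and annotation are not given in the sources used here.

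The saline and AngII files hold 1 list of 30883 transcripts and the AngII+ETH files another of 30036, of which 28886 are common. Of these, 8239 are assembled transcripts without a gene name, which held 10.4 to 15.7% of the common sum and were left out of the gene sums, so a gene whose reads went to them can be listed too low. Of the 20647 Ensembl transcripts, 20478 matched GENCODE M21 and were summed to 12911 genes, and 1171 genes have a transcript in 1 list only. Genes that share reads with near-identical copies are uncertain.

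The 11703 genes with a mean of 1 FPKM or more in at least 1 group were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1). All 18 libraries entered 1 fit, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. A count test was not used because the values are not counts. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. Of 55 gene lists, 48 had 5 or more tested genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Single values were compared with exact two-sided permutation tests over all 924 assignments of 12 libraries. The correlation between replicates across transcripts was 0.799 to 0.892.

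The groups, tests, gene lists, first alternatives and the rule for named genes were fixed before the data were examined. The rule took 15 cardiac genes whatever their result, and up to 5 genes at each end past the threshold whose values in one group all lay on one side of the other group's median. It also took up to 3 members, with the smallest p in the list's direction, of each list that passed, and was shortened for length to the 5 lists with the smallest p in each comparison. Plcd3, Klf10, Mybpc3, Acvrl1, Gm9531, Bmp10, Myl7, Myl2 and Adipoq were named after their values were seen. A gene among those the shortened rule named is not reported here. Replicates were numbered in accession order, which pairs no samples.

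The test was checked on simulated data, with 100 genes changed by 1 and 100 by 2 log2 units among 11703. For AngII against saline, AngII+ETH against AngII and AngII+ETH against saline it recovered 73, 78 and 75% of the smaller changes and 96% of the larger ones in each, with 2, 7 and 6 false calls. The adjusted threshold eases when many genes change, as in the simulation. In the real data 1, 0 and 1 genes passed, so these shares overstate how well a lone change would be found there. The simulated noise was independent between genes, without differences in chamber or adipose tissue between libraries. In the real data the estimated correlation within lists had a median of 0.27, so the check does not cover the list test or such differences. Alternatives covered scaling, trend, sample weights, the pseudocount (0.1), the filter, the genes and groups in the fit, the threshold and each library left out. Chamber and adipocyte covariates, the fit without 5 libraries and the transcript fits were added after the data had been seen.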

Results

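The series measured RNA in mouse cardiac tissue after 28 days of saline, angiotensin II (AngII, a peptide hormone that raises blood pressure, 500 ng per kg per min), or AngII with ethoxysanguinarine (ETH, a plant benzophenanthridine alkaloid, 10 mg per kg per day). Each of the 3 groups had 6 libraries of total RNA depleted of ribosomal RNA. The labels do not state that each library came from a separate animal, so p-values measure only the spread between these samples. The deposited values are per transcript, and their unit, taken here as FPKM (fragments per kilobase of transcript, scaled to library size), was inferred from the values. Depth is known only by inference: if the values are FPKM, 1 FPKM of a transcript of 1 kb stood for 63.5 to 80.4 fragments, depending on the library. Genes are given by symbol without positions, because the genome build was not given in the sources used here. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Levels are mean FPKM ± SD with n = 6 per group.

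The libraries differed in heart chamber markers within every group. Myl7, the atrial myosin light chain, was listed at 0 in saline replicate 5, AngII replicate 3 and AngII+ETH replicate 4. It lay between 455 and 3519 FPKM in the other 15 libraries. Myl2, the ventricular light chain, was 3.77 FPKM in saline replicate 6, 3.37 in AngII replicate 5 and 361 in saline replicate 4, and 1102 to 7060 in the others. Adipoq, an adipocyte hormone, reached 105 and 168 FPKM in saline replicates 4 and 6 and at most 20.4 in the others. The atrial minus ventricular marker level was 1.6 ± 2.89 log2 units in saline, 0.76 ± 2.45 in AngII and 0.17 ± 2.18 in AngII+ETH. It did not differ detectably between groups (exact two-sided permutation p = 0.556 for AngII against saline, 0.699 for AngII+ETH against AngII and 0.344 for AngII+ETH against saline). With this spread the tests do not show that the groups were balanced. The adipocyte marker level was 4.69 ± 1.97 log2 units in saline, 2.69 ± 0.32 in AngII and 3.38 ± 0.67 in AngII+ETH. Exact permutation p was 0.0216 for AngII against saline and 0.0325 for AngII+ETH against AngII, with an adjusted p of 0.0974 for each over the 6 tests.

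**Figure D1:**
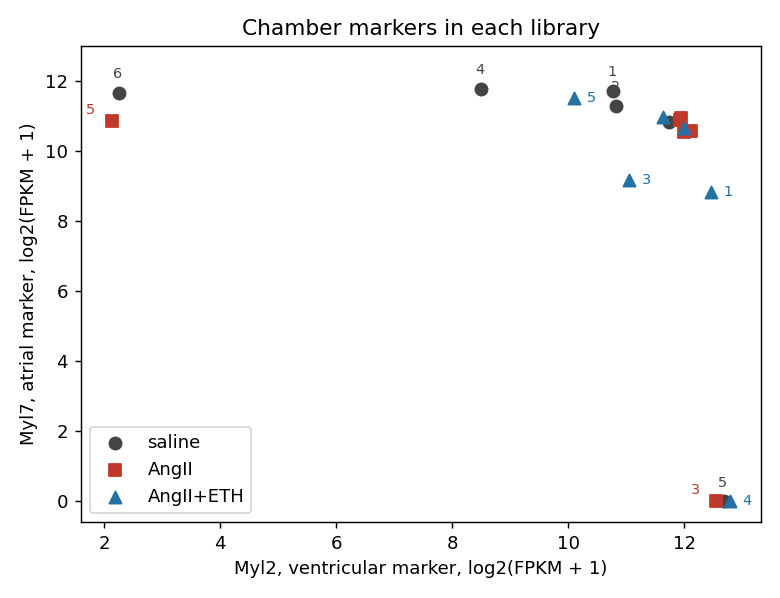
Each point is 1 library, with Myl2 on the horizontal and Myl7 on the vertical axis, both as log2(FPKM + 1), and numbers give the replicate of libraries that stand apart. Myl7 was listed at 0 in 3 libraries, 1 of each group, and Myl2 was under 10 FPKM in 1 saline and 1 AngII library.

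AngII against saline asked what the infusion changed. Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 15.3 ± 12.8 to 1.37 ± 0.609 FPKM (log2 fold change -2.46, SE 0.371, limma adjusted p = 0.0414). Every AngII library (0.668 to 2.46) lay below every saline library (4.23 to 34.9). The highest saline values, 27.9 and 34.9 FPKM, were in replicates 4 and 6, the saline libraries with high Adipoq. The other saline libraries were at 4.23 to 9.77. Sarcomere genes ranked above other genes, with 26 of 28 positive and a median log2 fold change of 0.56 (camera adjusted p = 7.48e-14, adjusted p = 0.122 with an estimated correlation). Among them were the muscle intermediate filament gene Des (1.03, SE 0.238), the muscle caveolar gene Cavin4 (1.23, SE 0.323) and the Z-disc gene Myoz2 (0.56, SE 0.180). Hypertrophy and fetal genes were positive in 17 of 19, median 0.72 (camera adjusted p = 8.96e-10, adjusted p = 0.168 with an estimated correlation). Ankrd23, a titin-binding ankyrin repeat protein, was 30.6 ± 25.1 FPKM in saline and 125 ± 80.6 in AngII (log2 fold change 2.18, SE 0.465, limma adjusted p = 0.321), and Hspb7, a small heat shock protein of muscle, had a log2 fold change of 0.97 (SE 0.222).

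Adipocyte genes were negative in 12 of 13, median -2.65 (camera adjusted p = 1.65e-06, adjusted p = 0.324 with an estimated correlation). Retn, which encodes resistin, was at -2.65 (SE 0.792), the lipid droplet gene Cidec at -2.97 (SE 0.900) and Lipe, hormone-sensitive lipase, at -1.54 (SE 0.472), alongside the high Adipoq of 2 saline libraries. All 7 tested neutrophil and mast cell genes were negative (camera adjusted p = 2.90e-05, adjusted p = 0.185 with an estimated correlation). The mast cell protease genes Tpsb2 and Mcpt4 had log2 fold changes of -1.28 (SE 0.342) and -1.21 (SE 0.375), and Cpa3, a mast cell carboxypeptidase, of -1.0 (SE 0.309). Heat shock genes were positive in 12 of 16 (camera adjusted p = 5.93e-05, adjusted p = 0.182 with an estimated correlation), with Hspb1 at 0.92 (SE 0.279), the co-chaperone Bag3 at 0.48 (SE 0.145) and Hspa8 at 0.39 (SE 0.121; 0.22, SE 0.128, without the 5 libraries with Myl7 or Myl2 under 10 FPKM). No member of these lists passed over all genes. Adjusted over the list alone, 7 sarcomere, 6 hypertrophy and 3 heat shock genes were higher, and 8 adipocyte, 4 neutrophil and mast cell and 1 heat shock gene lower. With chamber and adipocyte marker levels as covariates, chosen after seeing the data, the sarcomere and the neutrophil and mast cell lists no longer passed (camera adjusted p = 0.0523 for each), while the hypertrophy and fetal (0.000473) and heat shock (8.93e-05) lists did. The adipocyte list (0.998) was then tested against its own level. With the chamber covariate alone, the sarcomere and the neutrophil and mast cell lists passed at the preset correlation (camera adjusted p = 3.39e-11 and 1.19e-05).

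Of the fixed cardiac genes, the natriuretic peptide gene Nppb was 134 ± 65.4 FPKM in saline and 650 ± 682 in AngII (log2 fold change 1.90, SE 0.622, limma adjusted p = 0.488), with 2004 FPKM in AngII replicate 5 and at most 564 in the other AngII libraries. Without the 5 libraries with Myl7 or Myl2 under 10 FPKM its log2 fold change was 1.07 (SE 0.645). Acta1, skeletal actin, was 52.8 ± 81.0 and 360 ± 509 (2.62, SE 1.06, adjusted p = 0.508), with 1283 FPKM in AngII replicate 3 and at most 643 in the other AngII libraries, and 1.96 (SE 0.955) without those libraries. Nppa, Myh6, Myh7, Ankrd1, Ccn2, Tgfb1, Timp1, Ccl2 and Atp2a2 had log2 fold changes between 0.10 and 0.99. Without those libraries Nppa was at -0.004, Ankrd1 at 0.32, Ccn2 at 0.073, Tgfb1 at 0.049, Myh7 at 0.07, Ccl2 at 0.058, Atp2a2 at 0.045 and Timp1 at -0.38. With the chamber marker level as a covariate Nppa was at 1.30 (SE 0.382, limma adjusted p = 0.323), against 0.50 (SE 1.33) without it. The collagens Col1a1 and Col3a1 were at -0.34 and -0.59 and the matricellular gene Postn at -0.62 (-0.093, -0.34 and -0.32 with the chamber covariate, -0.51, -0.71 and -1.18 without those libraries), none of these 12 past the threshold. Nppa, the atrial natriuretic peptide gene, was 157 FPKM in saline replicate 5 and 331 in AngII replicate 3, where Myl7 was listed at 0. Myh6 was between 163 and 2020 FPKM across libraries. Unnamed assembled transcripts were left out of the gene sums, and whether any belongs to Myh6 is not known here. Il6 was not among the genes tested.

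In all, 1 of 11703 genes passed with limma (0 higher, 1 lower; 1 and 1 with median-of-ratios scaling or quantile normalization), and 1060 had an unadjusted p under 0.05 (384 higher, 676 lower). Of 48 lists, 16 passed camera with the preset correlation (10 up, 6 down; 5 up, 9 down after quantile normalization) and 0 with an estimated correlation. With fry 0 passed the test for one direction and 5 the test for change in either direction, namely glucocorticoid response, hypertrophy and fetal, sarcomere, heat shock, and muscle atrophy and ubiquitin ligase genes (adjusted p = 9.22e-06, 0.0243, 0.0402, 0.0402 and 0.0402). The glucocorticoid response list holds Angptl4 and had 10 of 16 genes positive, and fry does not compare a list with other genes. The Angptl4 call ended with only the 2 groups in the fit, at the same log2 fold change (-2.46, SE 0.425, adjusted p = 0.423), and likewise when every transcript of these 2 groups' files was also used (-2.50, SE 0.427, adjusted p = 0.418). It ended with chamber and adipocyte covariates (-1.69, SE 0.374, adjusted p = 0.463) and without the 5 libraries with Myl7 or Myl2 under 10 FPKM (-2.24, SE 0.419, adjusted p = 0.204). It also ended without saline replicate 1 or 4 or any 1 of AngII replicates 1 to 6, with log2 fold changes of -2.22 to -2.58 (limma adjusted p = 0.0578 to 0.161, 0 genes each). Without saline replicate 5, in which Myl7 was listed at 0, 11 genes passed.

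**Figure D2:**
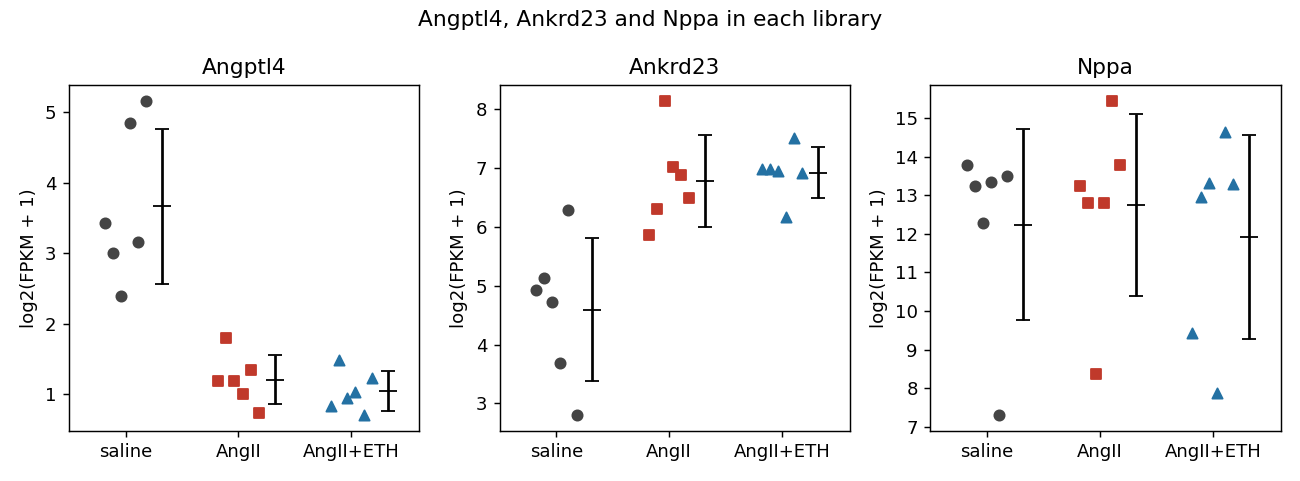
Points are libraries, and the bar at the right of each group is the mean and SD (n = 6), as log2(FPKM + 1), for Angptl4, Ankrd23 and Nppa. Angptl4 did not overlap between saline (4.23 to 34.9 FPKM) and AngII (0.668 to 2.46), and the lowest Nppa value of each group was in the library with Myl7 at 0.

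AngII+ETH against AngII asked what ETH changed in infused mice. All AngII+ETH files hold another transcript list than the saline and AngII files. A difference in processing therefore cannot be told apart from ETH in this comparison or in that against saline. Fibrillar collagen and matrix genes ranked above other genes in AngII+ETH, positive in 34 of 36 with a median log2 fold change of 0.54 (camera adjusted p = 5.67e-11, adjusted p = 0.691 with an estimated correlation). Col6a3, a collagen VI chain, was 6.4 ± 1.39 FPKM in AngII and 9.80 ± 2.97 in AngII+ETH (log2 fold change 0.52, SE 0.194), and Fbn1, the microfibril protein fibrillin, was at 0.79 (SE 0.300) and the collagen I gene Col1a2 at 2.19 (SE 0.962). Col1a2 varied widely within groups, from 0.951 to 40.6 FPKM in AngII, where Col1a1 was 27.8 to 106, and it was 0.00935 in saline replicate 2, where Col1a1 was 47.2. Macrophage genes were positive in 23 of 26, median 0.22 (camera adjusted p = 7.19e-06, adjusted p = 0.691 with an estimated correlation), including the fractalkine receptor Cx3cr1 (0.80, SE 0.239), the folate receptor gene Folr2 (0.79, SE 0.319) and the complement gene C1qc (0.44, SE 0.201). Interferon response genes were positive in 28 of 31, median 0.19 (camera adjusted p = 6.05e-05, adjusted p = 0.691 with an estimated correlation). Ifi27l2a, an interferon-induced gene, was at 1.25 (SE 0.50), the guanylate-binding protein gene Gbp3 at 0.61 (SE 0.265) and Usp18, an ISG15 protease, at 0.47 (SE 0.225). The interferon list no longer passed without AngII+ETH replicate 5 (camera adjusted p = 0.0513). The adipocyte marker level was higher in AngII+ETH than in AngII by 0.69 log2 units (exact permutation p = 0.0325, adjusted p = 0.0974).

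Circadian clock genes were negative in 11 of 17, median -0.09 (camera adjusted p = 6.05e-05, adjusted p = 0.310 with an estimated correlation). The clock output factor Dbp was 24.8 ± 8.93 FPKM in AngII and 12.1 ± 2.62 in AngII+ETH (log2 fold change -0.93, SE 0.256), the related factor Tef was at -0.33 (SE 0.099) and the clock repressor Per2 at -0.57 (SE 0.196). Adjusted over the list alone 2 clock genes were lower, against 0 over all genes. The time of day of collection is not among the sample details used here. A difference in it between the groups therefore cannot be told apart from ETH for these genes. Cholesterol synthesis genes were positive in 18 of 19, median 0.32 (camera adjusted p = 9.04e-05, adjusted p = 0.691 with an estimated correlation), among them Fdft1, squalene synthase (0.79, SE 0.372), and the sterol methyl oxidase gene Msmo1 (0.52, SE 0.245). Hypertrophy and fetal genes did not pass, with 10 of 19 positive (camera adjusted p = 0.930), but ranked above other genes without the 5 libraries (camera adjusted p = 0.00219, adjusted p = 0.459 with an estimated correlation). Col1a1 was 59.0 ± 33.4 FPKM in AngII and 105 ± 56.3 in AngII+ETH (log2 fold change 0.77, 95% interval -0.23 to 1.76), and Postn 27.7 ± 27.5 and 57.5 ± 46.9 (1.0, -0.47 to 2.46). Col3a1 was at 0.73 (-0.21 to 1.67), Nppa at -0.82 (-3.62 to 1.98), Nppb at -0.29 (-1.60 to 1.02) and Acta1 at 0.98 (-1.25 to 3.22). Without the 5 libraries Nppb was at 0.63, Nppa at -0.43 and Postn at 1.78, and with the chamber covariate Nppa was at -0.26 and Acta1 at 0.65. Myh6, Myh7, Ankrd1, Ccn2, Tgfb1, Timp1, Ccl2 and Atp2a2 lay between -0.27 and 0.44. Without the 5 libraries Ankrd1 was at 0.70, Ccn2 at 1.21, Tgfb1 at 0.13 and Timp1 at 0.85. Angptl4 did not differ detectably (exact two-sided permutation p = 0.385).

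With limma 0 of 11703 genes passed, and 224 had an unadjusted p under 0.05 (148 higher, 76 lower). Of 48 lists, 16 passed camera with the preset correlation (12 up, 4 down), 0 with an estimated correlation and 0 with fry, for one direction or for either. Without the 5 libraries 1 gene passed and was lower, Plcd3, a phospholipase C gene listed at 0 in all saline libraries. The lists that passed camera then numbered 24, with 12 gained, among them fibroblast and TGF-beta signalling genes (up) and oxidative phosphorylation and fatty acid oxidation genes (down; adjusted p = 3.11e-05, 0.000482, 8.86e-14 and 3.79e-11), and 0 passed with an estimated correlation (adjusted p = 0.431, 0.462, 0.459 and 0.431 for these 4). The heat shock, NADPH oxidase, neutrophil and mast cell, and adipocyte lists no longer passed (camera adjusted p = 0.164, 0.0706, 0.0774 and 0.158).

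AngII+ETH against saline asked how far the treated hearts differed from saline hearts. Angptl4 fell from 15.3 ± 12.8 FPKM to 1.09 ± 0.428 (log2 fold change -2.63, SE 0.371, limma adjusted p = 0.0175), and every AngII+ETH library (0.631 to 1.81) lay below every saline library. Sarcomere genes were positive in 25 of 28, median 0.52 (camera adjusted p = 8.12e-12, adjusted p = 0.161 with an estimated correlation), with Cavin4 at 1.22 (SE 0.323), Des at 0.88 (SE 0.238) and Myot, a Z-disc gene, at 1.60 (SE 0.483). Hypertrophy and fetal genes were positive in 18 of 19, median 0.81 (camera adjusted p = 3.39e-10, adjusted p = 0.161 with an estimated correlation), including Ankrd23 (2.32, SE 0.465), Hspb7 (0.97, SE 0.222) and Mybpc2, a fast muscle myosin binding protein (1.07, SE 0.265). Fibrillar collagen and matrix genes were positive in 33 of 36, median 0.48 (camera adjusted p = 2.43e-07, adjusted p = 0.537 with an estimated correlation). Prelp, a matrix proteoglycan, was at 1.79 (SE 0.664), Thbs4, a thrombospondin, at 1.84 (SE 0.713) and Cilp, a cartilage matrix protein, at 1.61 (SE 0.630).

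Activated fibroblast genes, a list that also holds Thbs4 and Cilp, were positive in 14 of 15, median 0.59 (camera adjusted p = 0.000283, adjusted p = 0.537 with an estimated correlation), with Cthrc1 at 0.91 (SE 0.470). Adipocyte genes were negative in 12 of 13, median -1.48 (camera adjusted p = 0.000607, adjusted p = 0.537 with an estimated correlation), with Lipe at -1.23 (SE 0.472), Pck1, a gluconeogenic enzyme, at -2.66 (SE 1.09) and Cidec at -1.99 (SE 0.900), alongside the high Adipoq of 2 saline libraries. Adjusted over the list alone, 4 sarcomere and 8 hypertrophy genes were higher, against 0 over all genes. Acta1 had a log2 fold change of 3.61 (SE 1.06, limma adjusted p = 0.417) and Nppb of 1.60 (SE 0.622, adjusted p = 0.539), while Nppa was at -0.32 (SE 1.33) and, with the chamber covariate, at 1.04 (SE 0.39, adjusted p = 0.413). Nppa was at -0.43 (SE 0.783) without the 5 libraries. Myh6, Myh7, Ankrd1, Col1a1, Col3a1, Postn, Ccn2, Tgfb1, Timp1, Ccl2 and Atp2a2 lay between 0.02 and 1.0, none past the threshold. With the chamber covariate Col1a1 was at 0.85, Col3a1 at 0.56, Postn at 0.90, Ankrd1 at 1.33, Ccn2 at 1.55, Timp1 at 1.07, Myh7 at -0.20 and Atp2a2 at -0.064. The same genes, in this order, were at 0.629, 0.306, 0.605, 1.018, 1.28, 0.471, 0.032 and -0.095 without the 5 libraries.

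With limma 1 of 11703 genes passed (0 higher, 1 lower), and 879 had an unadjusted p under 0.05 (410 higher, 469 lower). Of 48 lists, 27 passed camera with the preset correlation (19 up, 8 down) and 0 with an estimated correlation. With fry 0 passed the test for one direction and 3 the test for change in either direction, namely glucocorticoid response, circadian clock, and hypertrophy and fetal genes (adjusted p = 1.58e-07, 0.00157 and 0.0141). Angptl4 is among the 1171 genes with a transcript in only 1 of the transcript lists, and its call ended with only the 2 groups in the fit, at the same log2 fold change (-2.63, SE 0.419, adjusted p = 0.197), and without the 5 libraries (-2.38, SE 0.397, adjusted p = 0.117). Without AngII+ETH replicate 1, 3, 4, 5 or 6 it was -2.56 to -2.67 (limma adjusted p = 0.0506 to 0.0778, 0 genes each). Angptl4 still passed with the chamber covariate (-2.49, SE 0.368, limma adjusted p = 0.0428). It also passed with chamber and adipocyte covariates (-2.13, SE 0.324, limma adjusted p = 0.04085), both settings chosen after seeing the data. Without the 5 libraries Klf10 and Ankrd23 passed, and without saline replicate 5, in which Myl7 was listed at 0, 8 genes did.

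**Figure D3:**
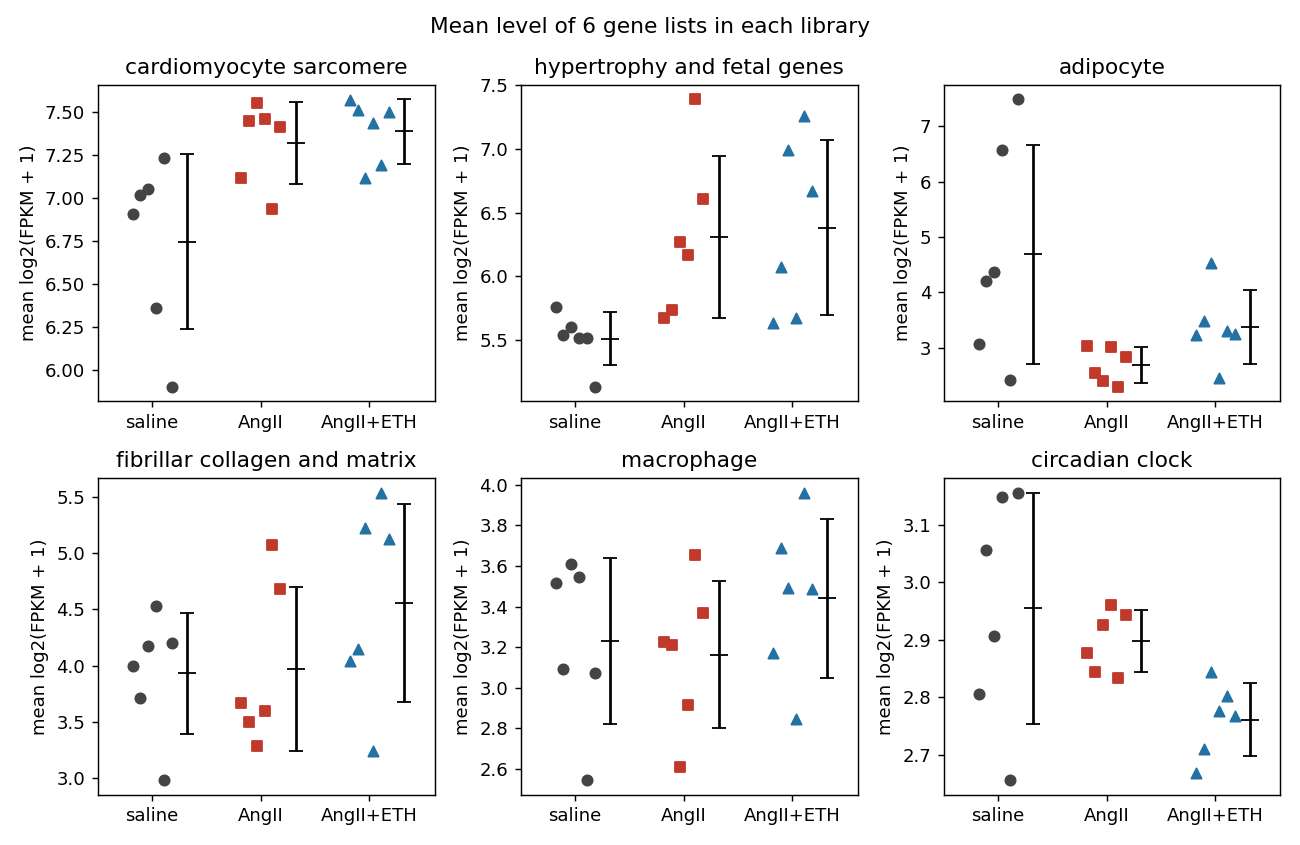
Points are the mean log2(FPKM + 1) over the tested genes of 6 lists in each library, with the mean and SD of each group (n = 6) at its right. Hypertrophy and fetal genes averaged 5.51 ± 0.21 in saline, 6.31 ± 0.64 in AngII and 6.38 ± 0.69 in AngII+ETH, and adipocyte genes 4.69 ± 1.97, 2.69 ± 0.32 and 3.38 ± 0.67.

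Whether genes changed by AngII moved the opposite way under ETH was asked with the AngII libraries split, since both contrasts share them. In 4 of 20 splits into 3 and 3 at least 1 gene passed, with opposite signs in 87.5% on average (50 to 100%). These genes were Plcd3 in all 4 splits and the myosin binding protein gene Mybpc3 in 1. Plcd3 was listed at 0 in all saline libraries and Mybpc3 at 0.107 ± 0.231 FPKM there, so this share rests on genes listed at the floor of 1 group. Unnamed assembled transcripts were left out of the gene sums, and whether any belongs to these genes is not known. The listed values may thus be too low. Over all 11703 genes the signs were opposite in 46.9% on average (37.9 to 54.1%), with a correlation across genes, which are not independent replicates, of 0.02 and a covariance of 0.0027. Without the split the signs were opposite in 61.5%, with a correlation of -0.39 and a covariance of -0.0288. In 100 simulated sets of unchanged groups the mean was 66.7% (38.7 to 86.6%), with a correlation of -0.48 and a covariance of -0.0383. Angptl4, the 1 gene past the threshold with all libraries, had the same sign in both contrasts.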

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

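The 3 patterns weighed here, and the covariate tests of them, were chosen after the group differences and marker levels had been seen. Among 159 groups of 6 values (53 genes in 3 groups), 16 had a sample far from the others, or 10.1%, where chance gives about 1 in 20. Without Myl7, Myl2 and Adipoq, which were named after their values were seen, these were 12 of 150 groups, or 8%. Of the chamber markers, Myl7 was listed at 0 in saline replicate 5, AngII replicate 3 and AngII+ETH replicate 4, and Myl2 was 3.37 FPKM in AngII replicate 5. Nppa was 157 FPKM in saline replicate 5 and 331 in AngII replicate 3, both with Myl7 at 0. AngII replicate 5 was also far above its group for Ccn2 (1554 FPKM, next 151), Tgfb1 (35.9, next 22.1) and Hspb1 (759, next 312). Cidec was 2.15 FPKM in AngII replicate 4 and Ccl2 4.21 in AngII+ETH replicate 2, each the highest of its group. Cx3cr1 was listed at 0 in saline replicate 6 and in AngII replicate 1. Gbp3 was 0.0505 FPKM in AngII replicate 1, Usp18 0.369 in saline replicate 2 and Prelp 1.37 in saline replicate 6, each the lowest of its group.

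Angptl4 differed between AngII and saline by -2.46 log2 units (SE 0.40, linear model). The difference was -2.38 (SE 0.39) with the chamber marker level as a covariate and -1.70 (SE 0.38) with the adipocyte level. This argues against either level as the whole cause, while a part from adipose tissue stays open. The chamber level does not separate the right from the left atrium. With both covariates limma gave -1.69 (SE 0.374, adjusted p = 0.463 against 0.0414 without them), so the call ended as the difference shrank at a like SE. The AngII infusion remains a candidate explanation, as does a difference in handling between the groups, which was not tested. In 3 of 100 splits of the 12 libraries, the real one among them, as many genes passed (1, highest other 1). This count only equals the highest of the other splits, and it was 0 with only the 2 groups in the fit. Chance is therefore less likely for this count but is not excluded. For AngII+ETH against saline as many genes passed in 7 of 100 splits (1, highest other 4), and chance was not excluded.

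Hypertrophy and fetal genes were 0.79 log2 units (SE 0.32) higher on average in AngII than in saline. With the chamber covariate the difference was 0.87 (SE 0.31), which argues against the atrial to ventricular balance as the whole cause. With the adipocyte covariate it was 0.73 (SE 0.41), and with both covariates the list still passed camera with the preset correlation (adjusted p = 0.000473), but the error of the difference is too wide to exclude adipose tissue beside the infusion. With an estimated correlation the list did not pass camera without covariates (adjusted p = 0.168), and this was not run with both covariates. The chamber covariate does not separate the right from the left atrium. Bmp10, a gene of the right atrium, was 0.0805 and 0.0324 FPKM in AngII replicates 5 and 6. Their mean list levels were 7.39 and 6.61, against 5.67 to 6.27 in the other AngII libraries. Which atrium was sampled was not tested and stays open beside the infusion. As many lists passed in 27 of 100 splits for AngII against saline (16, highest other 21, median 13 over the other 99), so chance was not excluded. For AngII+ETH against saline this held in 1 of 100 splits, the real one (27, highest other 25, median 15 over the other 99). Chance is therefore unlikely for this count, but several such counts were tested without correction, so it is not excluded. The count also does not show which lists differ. Since other splits of the same libraries often passed many lists, camera p-values with the preset correlation cannot be taken at face value here.

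Matrix genes were 0.59 log2 units (SE 0.42) higher in AngII+ETH than in AngII, a difference within 2 SE. It was 0.72 (SE 0.27) with the chamber covariate, which argues against the atrial to ventricular balance as the whole cause. It was 0.42 (SE 0.41) with the adipocyte covariate, so adipose tissue and ETH cannot be told apart here because of the error. Nor can a difference in processing be told apart from ETH, since the AngII+ETH files hold another transcript list than the AngII files. The chamber covariate does not separate the right from the left atrium. In AngII the matrix level was 5.07 and 4.68 in replicates 5 and 6, with Bmp10 at 0.0805 and 0.0324 FPKM. In replicates 1, 2 and 4, with Bmp10 at 381, 333 and 330, the level was 3.499 to 3.665. In AngII+ETH it was 4.04, 5.22 and 5.54 in replicates 1, 3 and 5 (Bmp10 0.0639, 3.14 and 1.30). Replicates 2 and 6 were at 4.15 and 5.12 (Bmp10 345 and 158). The atrium sampled was not tested and stays open. As many lists passed in 22 of 100 splits (16, highest other 25, median 10 over the other 99), so chance was not excluded. The count of genes was 0 (highest other 9), which all 100 splits reach by construction, so the splits say nothing about it.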

How the results depend on the processing

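Settings with covariates, without the 5 libraries with Myl7 or Myl2 under 10 FPKM, or on other transcripts were chosen after seeing the data. AngII against saline gave 1 gene, and 2 with median-of-ratios scaling or quantile normalization (Angptl4 and Gm9531), 3 with sample weights, 0 with only the 2 groups, 0 at an adjusted p under 0.01, 2 without the 5 libraries, 5 with the chamber covariate, 2 with both covariates, and 0 on single transcripts, 0 on every transcript of its files with only the 2 groups, where the smaller fit alone gave 0, and 0 on genes with the same transcripts in both lists, which leave Angptl4 out. AngII+ETH against AngII gave 0, and 1 without the 5 libraries. AngII+ETH against saline gave 1, and 4 with sample weights, 0 with only the 2 groups, 0 at an adjusted p under 0.01, 2 without the 5 libraries, 3 with both covariates, 2 on single transcripts (of Angptl4 and Acvrl1) and 0 on genes with the same transcripts. Leaving out 1 library gave 0 to 11, 0 to 0 and 0 to 8 genes, and 14 to 19, 13 to 20 and 19 to 26 lists, in the order of the comparisons above. The lists went from 16, 16 and 27 to 0, 0 and 0 with an estimated correlation (also without the 5 libraries, or with the chamber covariate), to 0, 0 and 0 with fry for one direction (5, 0 and 3 for either), and to 10 for AngII against saline with both covariates, where the adipocyte list is tested against its own level. They were 14, 17 and 20 with quantile normalization, 24, 24 and 20 without the 5 libraries, 19, 23 and 24 with the chamber covariate, and 22 and 20 for the other comparisons with both covariates. Opposite signs under ETH were 87.5% on average, 46.9% over all genes, 44.6% over the 500 genes with the smallest p and 0% for Angptl4 with all 6 AngII libraries. Of the fold changes of named genes, 406 kept direction and side of the threshold and 16, none past it, turned sign. In the same direction, 1 newly passed the threshold and 2 no longer passed. Atp2a2 turned under quantile normalization (-0.082, 0.018 and -0.064 in the 3 comparisons), and for AngII+ETH against saline also without the 5 libraries (-0.095) and with the chamber covariate (-0.064). Ccn2 turned in AngII+ETH against AngII with both scalings (-0.013 and -0.005). Without the 5 libraries Nppa (-0.004) and Timp1 (-0.38) turned in AngII against saline, and Nppb (0.63), Ankrd1 (0.70) and Tgfb1 (0.13) in AngII+ETH against AngII. With the chamber covariate Ankrd1 (0.067) and Tgfb1 (0.01) turned there, and Nppa (1.04) and Myh7 (-0.20) in AngII+ETH against saline. Beyond the smaller sets of genes or libraries, the cause was not tested. Depth was only inferred, so no counting error is given. The count tools planned for count data were not run. No paired analysis was possible because the labels give no replicate numbers.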

Other observations

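Lists outside the groups above also ranked apart with the preset correlation. In AngII against saline, endothelial genes were positive in 19 of 22 (camera adjusted p = 0.000165, adjusted p = 0.185 with an estimated correlation) and nerve and Schwann cell genes negative in 8 of 8 (0.00123, adjusted p = 0.505 with an estimated correlation). With chamber and adipocyte covariates, chosen after seeing the data, the endothelial list passed (0.00517) and the nerve and Schwann cell list did not (0.321). The adipocyte marker level was 4.69 ± 1.97 log2 units in saline and 2.69 ± 0.32 in AngII (n = 6). In AngII+ETH against AngII, activated fibroblast genes were positive in 15 of 15 (0.000134, adjusted p = 0.691 with an estimated correlation) and inflammatory cytokine and chemokine genes in 13 of 16 (0.000252, adjusted p = 0.351 with an estimated correlation). Mesothelial and epicardial genes were negative in 9 of 11 (0.00184, adjusted p = 0.692 with an estimated correlation) and glucocorticoid response genes in 11 of 16 (0.000545, adjusted p = 0.691 with an estimated correlation). The mesothelial list no longer passed without AngII replicate 5 (0.0885) or AngII+ETH replicate 4 (0.0698), nor the glucocorticoid list without AngII+ETH replicate 5 (0.0671).

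Bmp10, a gene of the right atrium, was 0.0805 FPKM in AngII replicate 5 and 0.0324 in AngII replicate 6. It was 0.0639, 3.14 and 1.30 in AngII+ETH replicates 1, 3 and 5. Myl7 was 455 FPKM or more in all of these libraries. In the other libraries with Myl7, Bmp10 was 18.1 to 868 FPKM in 5 of saline, 381, 333 and 330 in AngII replicates 1, 2 and 4, and 345 and 158 in AngII+ETH replicates 2 and 6. The differences between groups did not pass (limma adjusted p = 0.834 for AngII against saline, 1 for AngII+ETH against AngII and 0.777 for AngII+ETH against saline).

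Among other splits of the AngII and AngII+ETH libraries, the one with the most genes (9) had sides that differed by 1.08 log2 units in atrial minus ventricular level, a size reached in 32 of 100 splits, and by 0.14 in adipocyte level, reached in 76. Among those of the AngII+ETH and saline libraries, the one with the most genes (4, against 1 in the real split) had the largest chamber difference of the 100 (3.53) and an adipocyte difference of 1.66, reached in 6. With the chamber covariate the real split still gave 1 gene. These differences were computed after the counts were seen.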
